A study of Pimephales promelas with 22 samples.

How the data were processed

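RNA was measured in 22 liver samples of adult male fathead minnow (Pimephales promelas), a small freshwater fish widely used in toxicity testing. Per the labels, total RNA was extracted with Trizol, labelled with Cy3 and hybridised to Agilent arrays with 1 colour. Each array carried 1 sample. The title of each sample gives its river site and its number, and both were taken from there. NFSRD had 7 samples, PCFH had 7 and SFSR had 8, all of the year 2015. No number occurs at more than 1 site, so the samples were treated as unpaired. Nothing in the labels says how the fish were grouped in tanks or cages. The p-values set site differences against the spread between samples of a site, which may be partly technical. If the fish of a site shared a tank or cage, that spread leaves out differences between tanks or cages, and the p-values may be too small. Samples of the other sites that the series text names, NRWD and NRWU, were not analysed here.

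The scanner files hold spot intensity on a linear scale, made with Feature Extraction 10.1.1.1 per the file headers. The processed intensity was background-subtracted and detrended within the array per the file headers, with substitute values for spots not above background and no scaling between arrays. The same deposited files hold marks of 0 or 1 for each spot, which say whether it was well above background, saturated or an outlier among pixels or replicate spots. The deposited series table holds values that behave as log2, quantile-normalised over all 22 arrays per its header, with a minimum of 2.9 that recurs in every column. Each of its columns correlated best with the array of its own name, over the tested probes. How the authors treated background before that table was made is not given in the sources used here.

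The array holds 61053 spots outside the controls, with 49849 probe names and 44586 distinct sequences of 60 bases. The files give every probe its own ID in place of a gene name and call every description unknown. The given gene table of the species has no probe IDs or probe sequences. Genes were therefore not named. The 26 gene lists, the vitellogenin comparison and the named genes fixed before the data were examined could not be computed. At most 2 probe IDs that rose and 2 that fell are printed per comparison, with their sequences.

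The base-2 logarithm of the processed intensity was taken, and the 75th percentile over the spots outside the controls was subtracted on each array. Levels below are on this scale, where 0 is the 75th percentile of the array. Spots marked as outliers were set to missing, and the spots of a probe were averaged. A probe was tested when it was well above background on at least 7 of the 22 arrays, whatever their site, and had at least 4 values at each site. This left 25152 probes with 22141 distinct sequences. Tested probes that share at least 25 bases in a row on the same strand were joined into 19519 targets, of which 5206 had more than 1 probe. Over 2838 pairs of tested probes with 1 sequence, the log2 fold changes of NFSRD over PCFH correlated at 0.966 across probes, and their median difference was 0.055.

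Site means were fitted to all 22 arrays in 1 model with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend on intensity), and p-values were two-sided. NFSRD and SFSR were each compared with PCFH, the reference site in the series text, and with each other. A moderated F test compared the 3 sites. The threshold was a Benjamini-Hochberg adjusted p under 0.05 within a comparison. Printed probes are the 2 with the largest rise and the 2 with the largest fall past the threshold, a target being represented by the brightest of its probes that passed. This follows the rule fixed before the data were examined, with targets in place of gene names. No printed probe was dim on every array of a site, so no fold is given as a bound. Where a printed probe was dim on some arrays of a compared site, the number of arrays well above background is given. The difference then rests partly on dim values. Some of these may be substitutes, but which values were substituted was not read. No tested probe was saturated on any array.

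The number of arrays limits the precision. The median SD between samples of a site on the log2 scale was 0.50 at NFSRD, 0.57 at PCFH and 0.61 at SFSR. The median difference between 2 spots of a probe on an array lay between 0.094 and 0.202, over 4865 pairs of spots. The fit was tested on simulated data with the real levels and spreads of the 25152 probes, 200 of them changed, in 20 simulations for each comparison against PCFH. For NFSRD vs PCFH it recovered 5.45% of probes changed 1.5-fold, 27.8% of those changed 2-fold and 74.0% of those changed 4-fold, and 5.70% of calls were false. For SFSR vs PCFH the shares were 6.04%, 28.4% and 75.8%, and 5.19% of calls were false. In these simulations changes of 2-fold or less were mostly missed. The simulated noise was normal and independent between probes and arrays, so the false shares hold under those assumptions alone. The simulated fits made 75.4 calls on average for NFSRD vs PCFH, where the measured data gave 1507. The share recovered depends on the number of changed probes as well as on sample size, so it may differ in the measured data.

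The comparisons against PCFH share its arrays. Unchanged sites were simulated 1000 times by rotating the residuals of the fit, and the 7 PCFH arrays were also divided into 3 and 4 in all 35 ways. Lists of the lengths called were compared after ranking probes by the difference over the moderated SD. The scanner files place the arrays on 5 slides, in 2 rows and 4 columns, scanned on 2 days. Slide was tried as a fixed and as a random block. The alternatives chosen before the data were examined were normexp background correction (offset 50), quantile normalisation, the authors' table, no filter on dim probes, a filter requiring all 22 arrays, both slide blocks, array weights, fits of the compared sites alone, outlier spots kept, the plain one-way analysis of variance that the series text names, other thresholds and each array left out. Fits with slide row, slide column or scan day as a term, without 4 arrays of high background, and with 1 probe per target were added after seeing the data. Normexp adds its offset to every spot before the logarithm, which shrinks the log2 differences of dim probes by construction.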

Results

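Liver RNA of adult male fathead minnows was compared between 3 sites of the Shenandoah River watershed in Virginia. The title of the series names endocrine disruption and exposures of fish in a mobile laboratory as its subject. NFSRD lies on the North Fork near Woodstock, SFSR on the South Fork at Bentonville, and PCFH on Passage Creek at a fish hatchery. PCFH is the reference site. The arrays identify transcripts by probe ID alone, so the results describe probes and targets, a target being a set of probes with overlapping sequence.

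The number of probes well above background per array averaged 24830 ± 1337 (SD, n = 7) at NFSRD, 20318 ± 4349 (SD, n = 7) at PCFH and 21581 ± 4862 (SD, n = 8) at SFSR. The 75th percentile of signal ran from 81.0 to 258.2 over the 22 arrays. A raised background marked 4 arrays, PCFH replicates 62 and 63 and SFSR replicates 71 and 73. The interquartile range of their negative controls was 25.4 to 59.5 brightness units, against 3.02 to 7.25 on the other 18 arrays. They had 12954 to 16327 probes well above background, against 20085 to 26517 on the others. All 4 were scanned on day 1, with 1 other array. The first principal component held 13.6% of the variance. All 7 NFSRD arrays had scores from -116 to -24.3 on it and all 7 PCFH arrays had scores from 9.71 to 63.3. The SFSR arrays spread from -42.3 to 66.2.

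**Figure D1:**
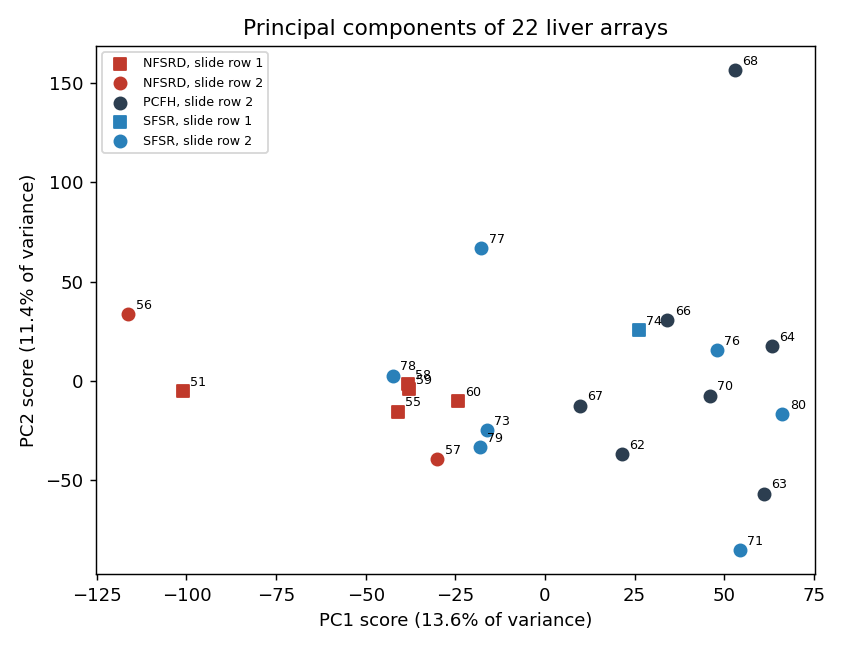
Scores of the 22 liver arrays on principal components 1 and 2 (13.6% and 11.4% of variance), 1 point per array, coloured by site, with squares for slide row 1, circles for slide row 2 and the replicate number beside each point. The NFSRD and PCFH arrays lie apart on component 1, the SFSR arrays overlap both, and PCFH replicate 68 lies apart on component 2 with a score of 156.5.

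The first comparison asked how liver transcripts at NFSRD differed from those at the reference site. Of the 25152 probes tested, 886 were higher and 621 were lower at NFSRD than at PCFH, 1507 in all. These probes belong to 1177 targets, 661 higher and 516 lower. The split moved with the scaling: normexp gave 644 probes higher and 331 lower, quantile normalisation 878 and 446. The median change of the probes that passed was 1.07 on the log2 scale, with quartiles of 0.82 and 1.56, which is 2.10-fold at the median. Falls were larger than rises at the upper end. At least a 4-fold change was seen for 48 probes that rose and 177 that fell, although fewer probes fell. Of these, 12 rises and 72 falls were well above background on every compared array. The size of the others rests partly on dim values, some of which may be substitutes. Normexp, whose offset shrinks the differences of dim probes, left 15 rises and 49 falls of that size, quantile normalisation 79 and 115. The balance also differed by brightness, which was not tested and was not counted under other scalings. Among tested probes with a mean signal below the array's 75th percentile, 256 rose and 261 fell. From 1 to 4 times that percentile 358 rose and 132 fell, and from 4 to 16 times 196 and 118. From 16 to 64 times 54 rose and 75 fell, and over 64 times 22 and 35. In 490 of the tested probes the NFSRD and PCFH values did not overlap, where chance gives 14.7 (0.058%). In 460 targets with more than 1 tested probe at least 1 probe passed. All probes changed in the same direction in 459 of these, and all passed in 307. Probes of a target overlap in sequence and were read on the same arrays, so their agreement does not replicate the site difference.

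The target with the largest rise past the threshold was represented by UF_Ppr_AF_108150 (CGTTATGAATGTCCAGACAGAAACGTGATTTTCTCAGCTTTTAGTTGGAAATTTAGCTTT). Its log2 level was 4.99 ± 1.22 (SD, n = 7) at NFSRD and 0.44 ± 1.49 (SD, n = 7) at PCFH, a 23.3-fold difference (log2 4.54, SE 0.93, adjusted p = 0.00955). Its signal was well above background on 7 of 7 NFSRD and 6 of 7 PCFH arrays. Its 2 further probes also rose and passed. The next was UF_Ppr_AF_116500 (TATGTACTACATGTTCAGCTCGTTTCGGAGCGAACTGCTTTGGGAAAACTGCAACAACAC), which was higher at NFSRD (log2 4.01, SE 0.89, adjusted p = 0.013). It was well above background on all 7 NFSRD arrays and on 1 of 7 PCFH arrays. Its level was 0.22 ± 0.86 (SD, n = 7) at NFSRD and -3.79 ± 1.63 (SD, n = 7) at PCFH. The largest fall was at UF_Ppr_AF_109272 (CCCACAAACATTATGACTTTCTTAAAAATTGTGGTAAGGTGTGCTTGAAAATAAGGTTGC), whose log2 level was -4.64 ± 3.46 (SD, n = 7) at NFSRD and 2.53 ± 3.45 (SD, n = 7) at PCFH (log2 difference -7.17, SE 1.97, adjusted p = 0.035). This probe was well above background on 1 of 7 NFSRD arrays and 6 of 7 PCFH arrays, so its mean describes few samples at either site. Its call was lost in 12 of the 22 fits that left out 1 array and under 6 of 15 other settings, with adjusted p up to 0.516. SINGLET_18666 (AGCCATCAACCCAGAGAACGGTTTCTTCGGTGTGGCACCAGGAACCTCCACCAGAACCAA) fell by 5.89 on the log2 scale (SE 1.12, adjusted p = 0.00696), from 1.12 ± 3.32 (SD, n = 7) at PCFH to -4.77 ± 1.1 (SD, n = 7) at NFSRD. It was well above background on 5 of 7 PCFH arrays and 1 of 7 NFSRD arrays. With slide row as a term, 3 of the 4 printed probes lost their calls: UF_Ppr_AF_108150 (log2 5.29, adjusted p = 0.054), UF_Ppr_AF_109272 (-3.56, adjusted p = 0.516) and SINGLET_18666 (-6.11, adjusted p = 0.0653). UF_Ppr_AF_116500 passed (5.14, adjusted p = 0.0464). The size of differences against dim arrays depended on the background correction. Normexp gave 1.59 for UF_Ppr_AF_116500, -3.78 for UF_Ppr_AF_109272 and -3.12 for SINGLET_18666.

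Array position was not balanced over the sites. Slide row 1 held 5 of the 7 NFSRD arrays, none of the PCFH arrays and 1 of the 8 SFSR arrays. With slide row as a term in the fit, 61 probes were higher and 64 lower at NFSRD than at PCFH. The probes called without the term all kept their direction with it, and their log2 fold changes had a median ratio of 1.03 to those without it. Over all tested probes the fold changes with and without the term correlated at 0.892. The median SE over tested probes rose from 0.322 to 0.433. Row is partly confounded with site, and its effect is estimated within NFSRD and SFSR alone, since PCFH has no array in row 1. The row term itself passed for 0 of the 25152 probes with limma and reached an unadjusted p under 0.05 for 735. Slide passed for 140 probes (2699 unadjusted), scan day for 207 (3351) and slide column for 0 (1549). Within slide row 2, 2 NFSRD arrays against 7 PCFH arrays gave 0 probes at the threshold with limma and 2940 at an unadjusted p under 0.05. Slide row 1 had no PCFH array to compare. With slide as a block 949 probes were higher and 664 lower, and with scan day as a block 931 and 653. For each of slides 2 to 5 the 500 probes with the smallest p were chosen on the other slides. Within the slide that was held out, 84.6%, 92%, 88.6% and 87.8% of them went the same way, with 1 to 3 NFSRD and 1 or 2 PCFH arrays per slide. The share that regrouped arrays would reach by slide was not computed. In a like test by slide row, regrouped NFSRD and PCFH arrays had a 95th percentile of 69.2% and a maximum of 83.4%. Without slide 3, which leaves 4 NFSRD and 6 PCFH arrays, limma called 0 probes and 3074 had an unadjusted p under 0.05. Slide 1 held a single array. The count depended on single arrays. It was 682 without NFSRD replicate 51, 950 without 55 and 676 without 56. It was 978 without PCFH replicate 63, 870 without 64, 991 without 66 and 898 without 70.

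The second comparison set SFSR against the reference site. Far fewer probes passed: 26 were higher and 20 were lower at SFSR, in 18 higher and 16 lower targets. Their median change was 1.28 on the log2 scale, 2.43-fold. None of the rises and 5 of the falls reached 4-fold. In 62 tested probes the SFSR and PCFH values did not overlap, where chance gives 7.82 (0.031%). CONTIG5175 (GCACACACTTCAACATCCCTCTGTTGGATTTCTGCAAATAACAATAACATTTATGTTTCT) rose most (log2 1.69, SE 0.30, adjusted p = 0.0257), from -1.91 ± 0.54 (SD, n = 6 of the 7 PCFH arrays) to -0.21 ± 0.34 (SD, n = 8). Of its arrays, 6 of 7 PCFH and 7 of 8 SFSR were well above background. With outlier spots kept its difference was 1.22 and the adjusted p was 0.263, and normexp gave 0.869 (adjusted p = 0.0603). Its signal at NFSRD was -1.73 ± 0.74 (SD, n = 7), and SFSR also exceeded NFSRD (log2 1.52, SE 0.29, adjusted p = 0.014). UF_Ppr_AF_105594 (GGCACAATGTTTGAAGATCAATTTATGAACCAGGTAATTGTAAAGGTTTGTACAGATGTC) was higher at SFSR (log2 1.67, SE 0.33, adjusted p = 0.0395) and was well above background on 3 of 7 PCFH and 7 of 8 SFSR arrays. Normexp gave it a difference of 0.697 (adjusted p = 0.186). It was higher at NFSRD than at PCFH as well (log2 1.56, SE 0.35, adjusted p = 0.0125). SINGLET_18680 (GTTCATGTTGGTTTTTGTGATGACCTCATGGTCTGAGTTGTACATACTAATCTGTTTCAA) fell by 2.54 on the log2 scale (SE 0.52, adjusted p = 0.0446), from 2.79 ± 0.86 (SD, n = 7) to 0.26 ± 0.93 (SD, n = 8). UF_Ppr_AF_106690 (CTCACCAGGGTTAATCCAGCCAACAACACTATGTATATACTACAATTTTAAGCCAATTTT) fell by 2.52 (SE 0.51, adjusted p = 0.0395), from 1.72 ± 0.83 (SD, n = 7) to -0.81 ± 0.72 (SD, n = 8), with 7 of 8 SFSR arrays well above background. Both of these were lower at NFSRD as well, by log2 differences of -2.72 (SE 0.53, adjusted p = 0.00809) and -3.11 (SE 0.52, adjusted p = 0.00336).

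The calls of CONTIG5175, UF_Ppr_AF_105594, SINGLET_18680 and UF_Ppr_AF_106690 were lost in 6, 14, 15 and 14 of the 22 fits that left out 1 array, with no change of direction. They were also lost under 6 of 15, 9 of 15, 9 of 16 and 6 of 15 other settings, and the highest adjusted p over all fits was 0.263, 0.186, 0.129 and 0.127. With slide as a block CONTIG5175 passed (log2 1.69, adjusted p = 0.044). The others kept log2 differences of 1.41, -2.31 and -2.35 (adjusted p = 0.0749, 0.0978 and 0.0721). Normexp gave -2.05 for SINGLET_18680 (adjusted p = 0.0603) and -1.99 for UF_Ppr_AF_106690, which passed (adjusted p = 0.041). The count of probes for SFSR also moved with the fit. It was 16, with 6 higher and 10 lower, without the 4 arrays of raised background. It was 26 with slide as a block, 20 with slide row as a term and 5 with slide column as a term, the SFSR arrays lying mostly in other columns than the PCFH arrays. Within slide row 2, 7 SFSR arrays against 7 PCFH arrays gave 3 probes higher and 7 lower. Probes chosen on the other slides went the same way in 75%, 82.4%, 82.0% and 64.6% of cases within slides 2, 3, 4 and 5. No share for regrouped arrays was computed, so these values cannot be told from chance. Without slide 3 limma called 0 probes, and 2346 had an unadjusted p under 0.05. Leaving out 1 array gave 96 probes without PCFH replicate 62, and 9, 11, 9, 20 and 12 without PCFH replicates 63, 64, 66, 68 and 70. It gave 29, 9, 7, 9, 29, 7 and 28 without SFSR replicates 71, 73, 74, 76, 77, 78 and 80, and 19 without NFSRD replicate 58. The direction of the split also moved with the scaling. Quantile normalisation gave 40 higher and 17 lower, and normexp background correction gave 3 higher and 11 lower.

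**Figure D2:**
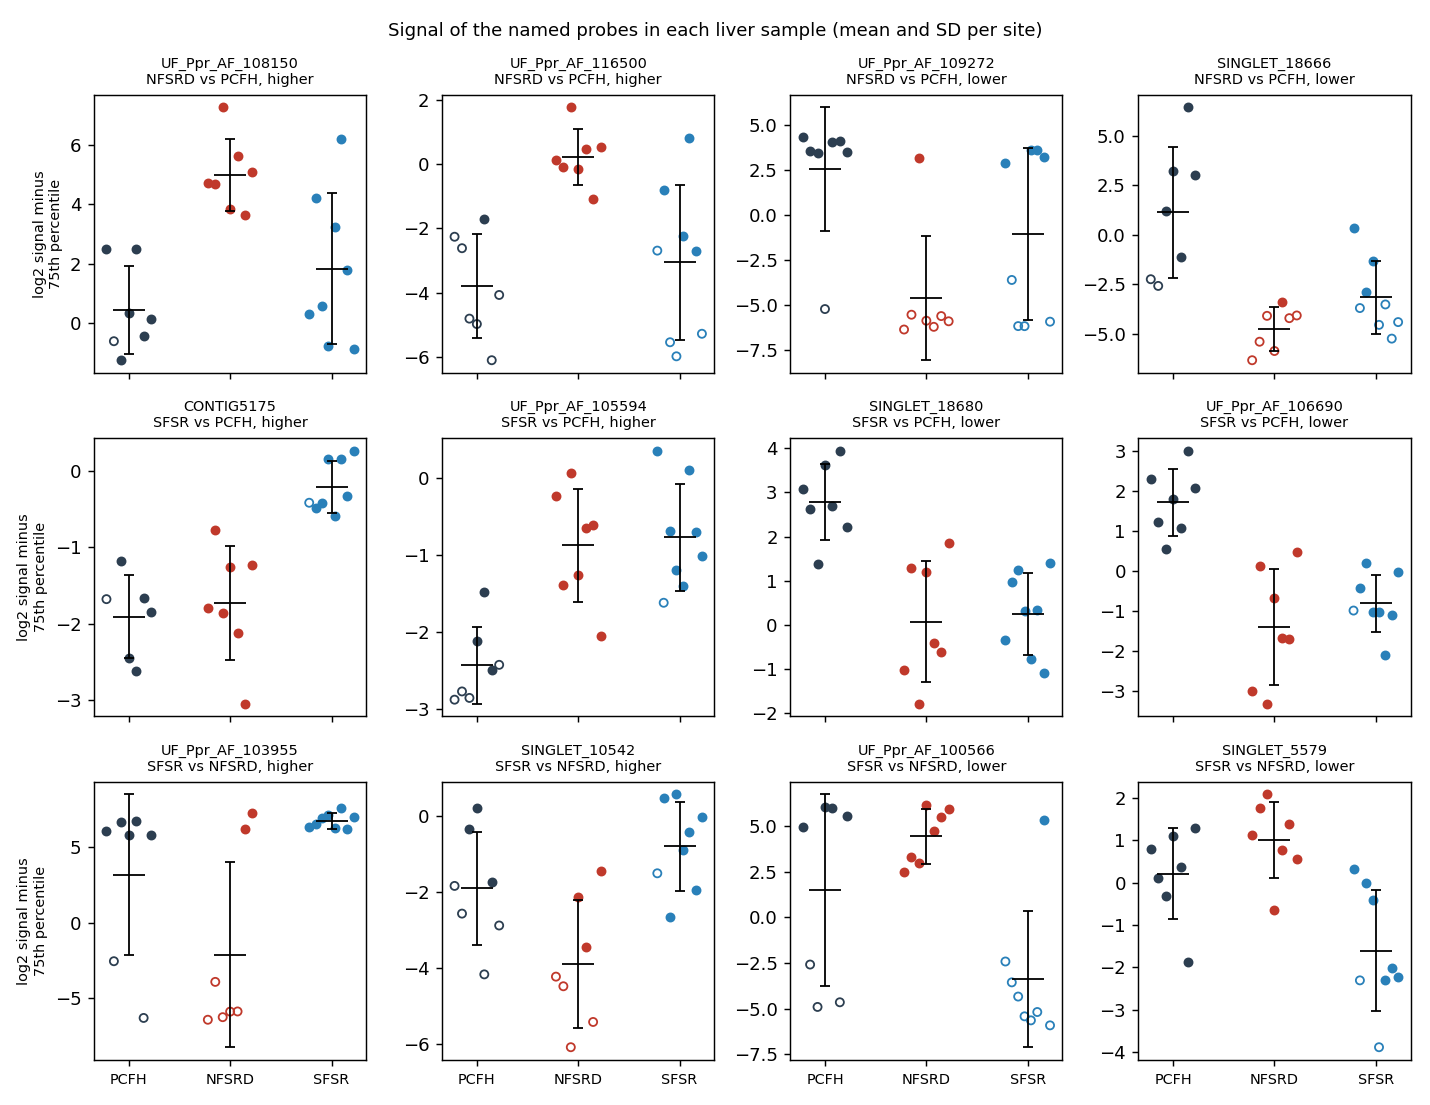
Log2 signal minus the array's 75th percentile for the 12 printed probes, 1 point per liver sample, filled where the probe was well above background and open where it was not, with the mean and SD of each site in black. The top row shows probes printed for NFSRD vs PCFH, the middle row SFSR vs PCFH and the bottom row SFSR vs NFSRD. UF_Ppr_AF_109272, UF_Ppr_AF_103955 and UF_Ppr_AF_100566 are bright in some samples of a site and near background in others.

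The comparison of the other sites with each other tested directly whether SFSR differed from NFSRD. At SFSR 129 probes were higher and 168 were lower, in 110 higher and 132 lower targets, with a median change of 1.02 on the log2 scale. UF_Ppr_AF_103955 (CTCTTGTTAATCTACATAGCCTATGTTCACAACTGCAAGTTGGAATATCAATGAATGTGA) showed the largest rise, from -2.13 ± 6.09 (SD, n = 7) at NFSRD to 6.70 ± 0.50 (SD, n = 8) at SFSR (log2 8.82, SE 2.17, adjusted p = 0.0453). It was well above background on 2 of 7 NFSRD, 5 of 7 PCFH and 8 of 8 SFSR arrays. SINGLET_10542 (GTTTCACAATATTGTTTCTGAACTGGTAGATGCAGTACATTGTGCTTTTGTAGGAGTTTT) was higher at SFSR (log2 3.10, SE 0.70, adjusted p = 0.0353). It was well above background on 3 of 7 NFSRD and 7 of 8 SFSR arrays, and normexp gave a difference of 1.12. The largest fall was at UF_Ppr_AF_100566 (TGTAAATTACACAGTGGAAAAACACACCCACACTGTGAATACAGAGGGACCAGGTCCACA), from 4.44 ± 1.51 (SD, n = 7) at NFSRD to -3.39 ± 3.72 (SD, n = 8) at SFSR (log2 -7.83, SE 1.82, adjusted p = 0.0396). It was well above background on 7 of 7 NFSRD, 4 of 7 PCFH and 1 of 8 SFSR arrays. SINGLET_5579 (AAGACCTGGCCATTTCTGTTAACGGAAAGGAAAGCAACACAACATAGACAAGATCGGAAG) was lower at SFSR (log2 -2.61, SE 0.57, adjusted p = 0.0307), with 7 of 7 NFSRD and 6 of 8 SFSR arrays well above background. The calls of UF_Ppr_AF_103955, SINGLET_10542, UF_Ppr_AF_100566 and SINGLET_5579 were lost in 17, 7, 10 and 4 of the 22 fits that left out 1 array and under 10, 9, 6 and 4 of 15 other settings. The highest adjusted p over all fits was 0.150, 0.186, 0.132 and 0.203. Normexp gave smaller differences of 5.87 for UF_Ppr_AF_103955, -5.10 for UF_Ppr_AF_100566 and -1.62 for SINGLET_5579, none of which passed. With slide as a block 104 probes were higher and 180 lower, with slide row as a term 14 and 21, and with slide column as a term 37 and 41. Within slide row 2, 2 NFSRD and 7 SFSR arrays gave 2 probes higher and 0 lower. Probes chosen on the other slides went the same way in 78.4%, 84.6%, 66.4% and 87.6% of cases within slides 2, 3, 4 and 5. Here too no share for regrouped arrays was computed to set beside these values. Without slide 3 limma called 0 probes, and 2078 had an unadjusted p under 0.05. The count was 147, 126, 77 and 159 without NFSRD replicates 51, 55, 56 and 58. It was 156, 107, 525 and 82 without SFSR replicates 74, 76, 78 and 80. Normexp background correction gave 16 higher and 49 lower.

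Across the 3 sites, 1091 probes passed the moderated F test, and 989 passed the plain one-way analysis of variance that the series text names. Of the 1091 probes, 847 also passed NFSRD vs PCFH, 292 passed SFSR vs NFSRD and 46 passed SFSR vs PCFH. NFSRD differed from both other sites in 141 probes and PCFH differed from both in 23. With slide row as a term 135 probes passed the F test. The count was 571, 597 and 341 without NFSRD replicates 51, 55 and 56, and 679, 621, 671 and 568 without PCFH replicates 63, 64, 66 and 70.

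The last comparison asked whether the changes at NFSRD and SFSR against PCFH ran together. In 23 probes both comparisons passed, 12 higher and 11 lower at both sites, and none passed in opposite directions. Independent lists of these sizes would share 0.92 higher and 0.49 lower, a value that leaves out the shared reference arrays. Unchanged sites set against the same reference arrays, with lists of the same lengths, shared 9.47 higher (95% of simulations from 3 to 17) and 6.19 lower (1 to 12). The same ranking of the measured values gave 13 and 11, within those limits. The simulated sites held no change, so this does not show that the shared reference arrays suffice. With the PCFH arrays divided between the comparisons the lists shared 8.64 higher (7 to 12.5 over 35 divisions) and 7.69 lower (4 to 10.5), against simulated upper limits of 1.5 and 1. The 12 shared rises had median log2 fold changes of 1.13 at NFSRD and 1.02 at SFSR, and the 11 shared falls had -1.65 and -1.93. None of the 23 differed between SFSR and NFSRD at an adjusted p under 0.05 with limma, and 1 had an unadjusted p under 0.05. They were chosen for passing both comparisons against the same PCFH arrays. That choice favours similar values at NFSRD and SFSR, so no equal response can be read from it. Of the 1484 probes that passed for NFSRD and not for SFSR, 141 also passed the direct test of SFSR vs NFSRD. Of the 23 that passed for SFSR and not for NFSRD, 13 did.

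Over all tested probes the fold changes of NFSRD and SFSR against PCFH correlated at 0.544 across probes, which are not independent replicates. Unchanged sites set against the same reference arrays gave a simulated 0.515 (95% of simulations from 0.339 to 0.667). The covariance was 0.196, against a simulated 0.106 (95% of simulations from 0.061 to 0.166), a difference of 0.090. With the PCFH arrays divided between the comparisons the correlation was 0.192 on average (0.103 to 0.248 over 35 divisions), against simulated values from -0.193 to 0.205. The covariance was then 0.090 on average (0.050 to 0.109 over 35 divisions). The average lay above the simulated upper limit of 0.068 and the lowest division below it. Where 500 probes were chosen on NFSRD against 4 PCFH arrays, 83.0% went the same way at SFSR against the other 3 (68.0% to 90.8% over divisions). Unchanged sites gave 50.2% on average and 95% of simulations from 28.8% to 72.2%, so some divisions lay inside those limits.

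**Figure D3:**
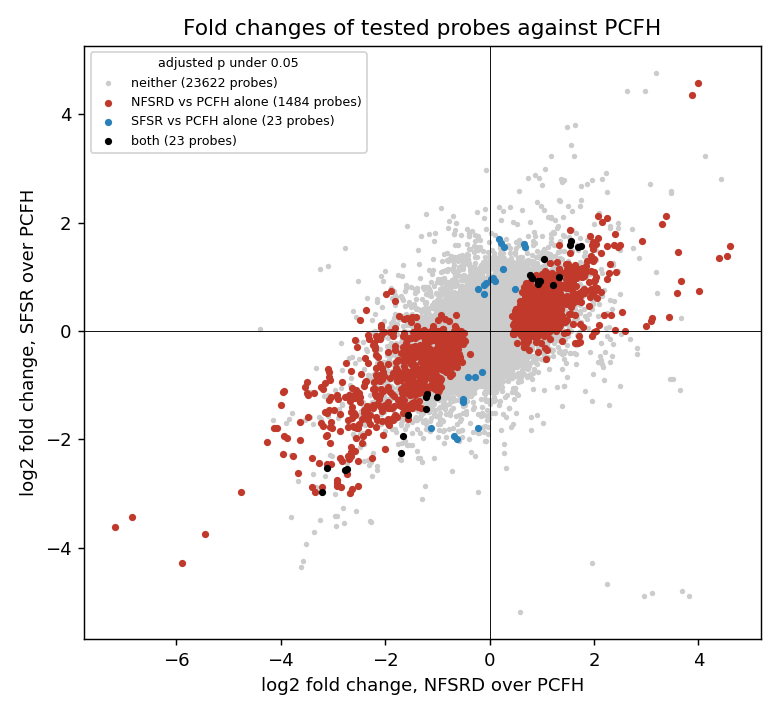
Log2 fold change of each tested probe at NFSRD over PCFH (horizontal) and SFSR over PCFH (vertical), 1 point per probe, coloured by which comparison passed an adjusted p under 0.05. The 1484 probes that passed for NFSRD alone, 23 for SFSR alone and 23 for both lie mostly in the quadrants of equal sign, and the shared reference arrays alone also tilt such a cloud.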

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

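Among 53 sets of values, 7 stood out because 1 sample lay far from the others of its site, as the gap to its nearest neighbour over the whole range. Chance gives about 1 in 20 such sets. UF_Ppr_AF_109272 accounts for 2 of them. At NFSRD, replicate 56 had a log2 level of 3.17 where the other 6 lay from -6.39 to -5.56, a gap of 0.914 of the range. At PCFH, replicate 66 had -5.25 where the others lay from 3.46 to 4.30, a gap of 0.912. At SFSR, UF_Ppr_AF_100566 had 5.33 in replicate 79 and -5.92 to -2.42 in the others, a gap of 0.689.

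PCFH replicate 68 correlated least with its site, with a median of 0.910 across probes against 0.932 to 0.941 for the others (gap 0.714). It also lay apart on the second principal component, at 156.5 against -56.7 to 30.6 (gap 0.590). SFSR replicate 71, an array of raised background and the single array of slide 1, had a median correlation of 0.906 with its site against 0.918 to 0.926 (gap 0.612). Its 2 spots per probe differed by a median of 0.202 against 0.095 to 0.145 in the others (gap 0.529).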

How the results depend on the processing

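Slide row, slide column, scan day, 1 probe per target and the removal of the 4 arrays of raised background were chosen after seeing the data. Gene lists and vitellogenin gave no value under any setting, because the files do not pair probes with genes. No paired analysis was possible because no replicate number occurs at more than 1 site. For NFSRD vs PCFH, 14 of 18 alternatives stayed within 1.5 times of 1507 probes. The exceptions were normexp (975), no filter on dim probes (856), slide row (125) and an adjusted p under 0.10 (2659). With slide row the median SE rose from 0.322 to 0.433. The fold changes of the called probes had a median ratio of 1.03 to those without it, but UF_Ppr_AF_109272 went from -7.17 to -3.56. With no filter 49849 probes shared the adjustment, and the median fold change over all of them was -0.493 for NFSRD vs PCFH and 0.406 for SFSR vs NFSRD, so the values of dim probes are offset between sites. For SFSR vs PCFH (46 probes) normexp gave 14, no filter 10, the filter on all 22 arrays 28, slide as a block 26, the 2 sites alone 30, an adjusted p under 0.10 196, no arrays of raised background 16, slide row 20, slide column 5 and 1 probe per target 28, and 72 probes passed in the authors' table. For SFSR vs NFSRD (297 probes) normexp gave 65, no filter 108, the filter on all 22 arrays 510, the 2 sites alone 113, an adjusted p under 0.10 995, slide row 35 and slide column 78. The F test (1091 probes) gave 537 with normexp, 512 with no filter, 2523 at an adjusted p under 0.10 and 135 with slide row. The correlation of fold changes moved from 0.544 to 0.669 with slide column. An adjusted p under 0.10 raises a count by construction. The fit of 1 probe per target counts targets, and 34 targets held a probe that passed for SFSR vs PCFH in the main fit. The cause was not tested for the remaining changes. Leaving out single arrays gave 676 to 1702 probes for NFSRD vs PCFH, 7 to 96 for SFSR vs PCFH, 77 to 525 for SFSR vs NFSRD and 341 to 1380 for the F test, and correlations of 0.495 to 0.593.

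Quantile normalisation moved the median NFSRD over PCFH fold change of all tested probes to 0.107 from 0.005, and 1147 of its 1324 calls were among the 1507. No printed probe changed direction under any setting, although 67 of 181 values of printed probes no longer passed. Signal over background limits what dim probes can show: 13724 of the 49849 probes were well above background on no array.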

Other observations

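The tests of high background, of overlap with a divided reference and the fits with slide row were chosen after the counts had been seen. Some targets were bright in several samples and near background in others, with no values between. A gap of at least 8-fold, with 3 or more samples on each side, was found in 81 targets among 24899 probes without missing values. Each sample was bright for 34 to 56 of the 81. UF_Ppr_AF_100566 was bright in 7 NFSRD, 4 PCFH and 1 SFSR samples and had the smallest permutation p for uneven spread over sites (p = 0.0029, adjusted p = 0.235 over 81 targets). UF_Ppr_AF_103955 was bright in 2 NFSRD, 5 PCFH and 8 SFSR samples (permutation p = 0.0075, adjusted p = 0.304). No target passed after adjustment. The hypothesis that fish differ for reasons unrelated to site was tested by shuffling the site labels. The observed 10 targets with p under 0.05 lay just above the 95th percentile of 9 under 10000 shuffles, which gave as many in 3.35% of cases. A link with site for some of these targets may therefore exist, and which ones is open. A sequence variant under the probe or the loss of a gene was not tested, since no genome sequence was given.

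The count of 1507 probes for NFSRD vs PCFH was set against chance and technical explanations. Of 100 splits of the 14 arrays, the real one included, 1 gave as many, and the highest of the others gave 2. Chance is therefore an unlikely source of the count, if the samples of a site are independent. The splits cannot tell a site difference from an effect of a tank or cage shared by the fish of a site. The position of the arrays was tested with 500 probes chosen on the 5 NFSRD arrays of slide row 1 against 4 PCFH arrays. In the 2 NFSRD arrays of slide row 2 against the other 3 PCFH arrays, 94.0% of them went the same way (91.6% to 95.8% over 35 divisions), where regrouped arrays gave 49.3% on average and a 95th percentile of 69.2%. That argues against slide row as the whole cause, and so does the count of 1220 without the 4 arrays of raised background against those arrays. A part played by slide row stays open, since row is partly confounded with site. The count was 125 with row as a term. The called probes kept their direction, with a median ratio of fold changes of 1.03, and the median SE rose from 0.322 to 0.433. The row term itself passed for 0 probes. The fall in the count is therefore not by itself a measure of a row effect. Both NFSRD arrays of slide row 2 also lay on slide 3. Without slide 3, with 4 NFSRD and 6 PCFH arrays left, limma called 0 probes. It called 637, 1034 and 377 without slides 2, 4 and 5. Of 500 probes chosen without slide 3, 92% went the same way within it, with no share for regrouped arrays beside that. A part played by slide 3 stays open. Tanks or cages shared within a site stay open too, as does any difference between the sites themselves, since each site is a single place.

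For SFSR vs PCFH, 1 of 100 splits of the 15 arrays gave 46 probes or more, the real one, and the highest other gave 12. For the F test, 1 of 100 splits gave 1091 or more, and the highest other gave 2. Chance is therefore an unlikely source of both counts, if the samples of a site are independent. Random splits cannot tell a site difference from array layout. The SFSR arrays lay mostly in other slide columns than the PCFH arrays. With slide column as a term 5 probes passed for SFSR vs PCFH, while the term itself passed for 0 probes. Leaving out 1 array gave 7 to 96 probes for that comparison. With slide row as a term 135 probes passed the F test. Slide column and slide row stay open. For SFSR vs NFSRD, 2 of 100 splits gave 297 or more. The other one gave 354 and kept 14 of the 15 arrays parted as the sites are, with SFSR replicate 77 moved to the NFSRD side. Chance is an unlikely source of that count too, on the same assumption, although its size follows single NFSRD and SFSR arrays. Array layout stays open here as well. The count was 35 with slide row and 78 with slide column as a term.

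The SFSR arrays did not lie together on the first principal component. Replicates 73, 77, 78 and 79 had scores of -16.1, -17.7, -42.3 and -18.2, and replicates 71, 74, 76 and 80 had 54.3, 26.3, 48.0 and 66.2.

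The fold changes at NFSRD and SFSR may share a part that the reference arrays do not create, or the shared PCFH arrays may account for it. With those arrays divided the correlation was 0.192, inside the simulated limits of -0.193 and 0.205. The simulated sites held no change, while changes at NFSRD alone would tend to lower a measured correlation. That test therefore neither excludes the shared arrays nor shows that they suffice. The covariance under the same division, 0.090 on average, lay above its simulated upper limit of 0.068, although the lowest of 35 divisions, 0.050, lay below it. These measures differ, and over all probes the explanations cannot be told apart from 7 reference arrays. For the top of the lists, 8.64 shared higher probes under division, with at least 7 in each division, lay above the simulated limit of 1.5, which argues against the shared arrays as the whole cause of that overlap. Other structure that NFSRD and SFSR arrays share stays open.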
